A study of Mus musculus with 40 samples.

How the data were processed

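RNA from single mouse embryos was sequenced with the SMART-seq2 protocol, which makes libraries from full-length cDNA without marking strand and without molecular identifiers. Zygotes were injected 17 to 18 hours after hCG with 20 uM control siRNA (siCon) or siRNA against Rif1 (siRif1) and cultured at 37 °C in 5% CO2. Embryos were collected at the 4-cell stage (63 hours after hCG) or the 8-cell stage (70 hours after hCG), and ERCC spike-in RNA was present in the lysis buffer. The 40 libraries, 1 per embryo, formed 4 groups taken from the labels: 7 siCon and 13 siRif1 embryos at the 4-cell stage, and 8 siCon and 12 siRif1 embryos at the 8-cell stage.

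The deposited tables hold raw read counts per gene that the authors made with STAR 2.7.6a, GRCm38 per the submitters' processing notes. Their annotation release is not given in the sources used here. Each table had 55487 mouse gene entries, 92 ERCC entries and 4 summary entries for reads that were not assigned to a gene. The strand columns held 49.7% to 51.2% of their sum on 1 strand, so the unstranded counts were used, and reads from genes that overlap on opposite strands could not be separated. Gene symbols, positions and biotypes came from GENCODE M21, which named 55227 of the gene entries.

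Library totals, detected genes, mitochondrial and ERCC shares, the summary entries and the share of counts in the 50 most abundant genes were compared between siRif1 and siCon within each stage by two-sided permutation tests, exact with groups under 10, with Benjamini-Hochberg adjustment over the 22 tests. No pair of libraries was a duplicate by a chi-square comparison of counts, whose lowest value per degree of freedom was 7.97.

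Differential expression was tested with edgeR 4.0.16 on counts normalised by TMM. Genes were kept by filterByExpr by group with a minimum count of 10, which left 11844 genes. A quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to all 40 libraries, and an adjusted p below 0.05 (Benjamini-Hochberg) was the threshold. The contrasts were siRif1 against siCon at the 4-cell stage, siRif1 against siCon at the 8-cell stage, 8-cell against 4-cell siCon embryos, and the siRNA by stage interaction, which is the 8-cell siRif1 effect minus the 4-cell effect. Fold changes are log2 values with the standard error (SE) of the model. Levels are CPM values scaled by TMM, as mean ± SD over embryos, and log2 CPM used a prior count of 2.

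Before the data were examined, 22 gene lists were fixed: 2-cell and Zscan4 genes, maternal oocyte transcripts, trophectoderm and compaction, pluripotency, primitive endoderm, DNA replication, p53 targets, double-strand break repair, mitotic cell cycle, heterochromatin and DNA methylation, imprinted genes, interferon-stimulated genes, small RNA pathway, nucleolus and ribosome biogenesis, endogenous retrovirus and LINE restriction, nuclear oxidative phosphorylation, heat shock and unfolded protein, cumulus and granulosa markers, sex-linked genes, mitochondrially encoded genes, cytosolic ribosomal proteins and replication-dependent histones. The histone list had 3 tested members, under the minimum of 5, and was not tested, so 21 lists were. Lists were tested with camera from limma 3.58.1 (preset correlation 0.01), which compares the members with the other genes, adjusted over the 21 lists. Camera with an estimated correlation and fry, which asks whether the members move 1 way on balance, were run beside it. The number of members past the threshold was counted over all genes and again adjusted over the list alone.

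The rule for naming genes was also fixed beforehand. It took Rif1, and in each group comparison the 10 largest increases and 10 largest decreases among genes past the threshold with a mean log2 CPM of at least 3 and an annotated symbol. It also took up to 2 members each way of every list among those past the threshold, or up to 2 with the smallest p where none passed, and the 5 genes with the smallest adjusted p for the interaction. Not every gene that the rule takes is printed. For lists with no member past the threshold, values are given chiefly where the list as a whole passed the camera test. Gpr137b and the single imprinted genes and Xist given for individual embryos lie outside this rule and were chosen after their values were seen.

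The stage score was the mean log2 CPM of genes higher at the 8-cell stage minus that of genes lower, with genes chosen in odd-numbered siCon embryos (adjusted p below 0.05 and at least 2-fold) and siRif1 embryos compared with even-numbered siCon embryos. The ratio of mouse gene counts to ERCC counts was compared as log2. Both used exact two-sided permutation tests of the mean. Correlations across embryos used 100000 permutations and 10000 bootstrap resamples.

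Alternatives fixed beforehand were DESeq2 size factors (RLE) in edgeR, no filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, a fit of the compared groups alone, a replicate block, omission of shallow libraries (under 25% of the median gene count or 60% of the median number of detected genes, which was 1 library), omission of genes on chromosomes X and Y, ERCC totals as size factors, a 2-fold minimum, and leaving out each library in turn. Omission of siCon 4-cell embryos 3 and 7, and Y-linked expression as a covariate, were added after seeing the data. Each count of genes was also compared with 100 splits of the same libraries into groups of the same sizes.

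The models were tested on simulated data with 200 changed genes. At a true change of 4-fold, edgeR recovered 81.8% of changed genes for the 4-cell contrast, 74.2% for the 8-cell contrast, 69.7% for the stage contrast and 66.7% for the interaction, and at 2-fold 43.3%, 41.8%, 37.3% and 25.4%. At 1.5-fold it recovered 2.99% to 5.97%. Unchanged genes made up 5, 2, 3 and 6 of the calls, and with no list changed 0 of 21 lists were called in each contrast. With the maternal list lowered by 0.5 in siRif1 4-cell embryos, 2 lists including it were called in the 4-cell contrast. Simulated genes were drawn independently of each other, without outlying embryos. These runs therefore do not show how often correlated lists, or genes with outlying embryos present, are called falsely. Other tools were R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and Matplotlib 3.10.9.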

Results

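Gene counts were measured in 40 single mouse embryos at the 4-cell and 8-cell stages after siRNA injection at the zygote stage. The 4-cell stage had 7 control (siCon) and 13 Rif1 siRNA (siRif1) embryos, and the 8-cell stage had 8 siCon and 12 siRif1 embryos. Counts on mouse genes ranged from 704863 to 8890551 per embryo, with a median of 3186068.5. They ran from 2396168 to 3424858 in the siCon 4-cell group, from 704863 to 8890551 in the siRif1 4-cell group, from 2140880 to 4240507 in the siCon 8-cell group and from 1479657 to 4417902 in the siRif1 8-cell group. The median embryo had 17188.5 detected genes. None of 22 permutation tests of library quality between siRif1 and siCon embryos passed the threshold, with a smallest adjusted p of 0.89. The counts come from reads without molecular identifiers, so floors cover counting error only, while bootstrap intervals cover the spread between embryos. The labels do not say that embryos came from separate litters or injection days, so each p measures the spread between these embryos.

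Rif1, which encodes a regulator of replication timing and of double-strand break repair, was the siRNA target (ENSMUSG00000036202, chromosome 2, 52072832 to 52122383, GRCm38). At the 4-cell stage its transcript fell from 428 ± 107 CPM in siCon embryos (SD, n = 7) to 178 ± 94.5 CPM in siRif1 embryos (n = 13), or 41.5% of the control mean. The log2 fold change was -1.26 (SE 0.24, edgeR adjusted p = 0.0064), and 11 of 13 siRif1 embryos lay below all controls. At the 8-cell stage Rif1 was at 314 ± 42.6 CPM in siCon embryos (n = 8) and 220 ± 92.9 CPM in siRif1 embryos (n = 12), or 70.1% of the control mean, and 9 of 12 lay below all controls. This 8-cell difference did not pass the threshold (log2 fold change -0.52, SE 0.24, edgeR p = 0.035, adjusted p = 0.999). The effects at the 2 stages differed by 0.75 (SE 0.34, interaction p = 0.034, adjusted p = 0.74 in edgeR). The 4-cell call ended in a fit of the compared groups alone (-1.27, adjusted p = 0.060) and with ERCC totals as size factors (-1.10, adjusted p = 0.60). It also ended with a replicate block, although replicate numbers did not pair samples.

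**Figure D1:**
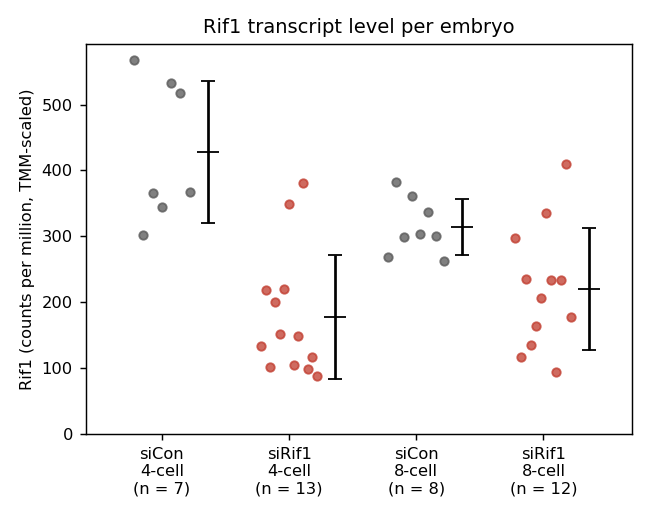
Rif1 level in CPM (vertical axis) in each embryo (points) of the 4 groups, with the mean and SD (bars). The 13 siRif1 4-cell embryos average 178 CPM against 428 CPM in the 7 controls, and 11 of them lie below every control.

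The 4-cell comparison of siRif1 with siCon embryos asked which transcripts differed after depletion of Rif1. In edgeR 67 of 11844 genes changed, 15 higher and 52 lower in siRif1 embryos. Of the genes that fell, 5 belonged to the fixed list of maternal oocyte transcripts. Bmp15, an oocyte-secreted growth factor (ENSMUSG00000023279, chromosome X, 6314107 to 6320721), was at 100 ± 159 CPM in siCon (n = 7) and 15.1 ± 9.42 CPM in siRif1 embryos (n = 13), with a log2 fold change of -2.72 (SE 0.48, adjusted p = 0.0042). Btg4, an adaptor of the deadenylase that clears maternal mRNA (ENSMUSG00000032056, chromosome 9, 51060901 to 51119875), went from 147 ± 212 to 30.2 ± 11.2 CPM (-2.28, SE 0.44, adjusted p = 0.0087). Zbed3, a maternal-effect gene, went from 594 ± 816 to 87.5 ± 68.0 CPM (-2.75, adjusted p = 0.014). The wide SD of the controls came with siCon embryos 3 and 7. Without them Bmp15 was at -0.92, Btg4 at -0.66 and Zbed3 at -1.04, and none of the 3 passed the threshold.

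Other named genes kept most of their change without siCon embryos 3 and 7, although no longer past the threshold, and were grouped here after their values were seen. H2afx, the histone variant phosphorylated at DNA breaks (ENSMUSG00000049932, chromosome 9, 44334694 to 44336077), fell from 159 ± 101 to 47.9 ± 41.7 CPM, a log2 fold change of -1.70 (SE 0.37, adjusted p = 0.019), and was -1.75 without both embryos (adjusted p = 0.11). Sdf2l1, a component of the chaperone complex of the endoplasmic reticulum, fell by 1.43 on the log2 scale (SE 0.28, adjusted p = 0.0087), and the value was -1.22 without them (adjusted p = 0.16). Among genes that rose, Cmtm7 was 1.41 higher (SE 0.27, adjusted p = 0.0087) and 1.26 without them (adjusted p = 0.059). Gorasp2, a Golgi stacking protein gene, was 0.79 higher (adjusted p = 0.011) and 0.75 without them (adjusted p = 0.11). Resf1, a retroelement silencing factor, was 0.81 higher and 0.92 without them (adjusted p = 0.15), and Jarid2, a partner of Polycomb repressive complexes, 0.86 and 0.76 (adjusted p = 0.26). Vnn1, a pantetheinase, was 1.93 higher (SE 0.38) and 1.48 without them (adjusted p = 0.11). Pax6, a homeodomain transcription factor, was 2.36 higher and 1.83 without them (adjusted p = 0.30).

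The other named increases were Pdgfa (2.09), Diaph2 (1.82), Kdelr3 (1.68) and Eef2kmt (1.45). The other named decreases were C86187 (-2.67), the nuclear receptor coactivator Ncoa2 (-2.65), B3gntl1 (-1.93), Dhcr7 of cholesterol synthesis (-1.92), D6Ertd527e (-1.86), the mitochondrial arginase Arg2 of the 2-cell list (-2.76) and the checkpoint kinase Chek1 (-0.83). Without siCon embryos 3 and 7 all these decreases lost their call: C86187 was at -0.52, Ncoa2 at -0.69, D6Ertd527e at -0.56, Arg2 at -0.76 and Chek1 at -0.29, and B3gntl1 and Dhcr7 turned positive (0.26 and 0.26). Pdgfa, Diaph2 (1.33), Kdelr3 (1.23) and Eef2kmt (1.44) lost theirs too, although Diaph2, Kdelr3 and Eef2kmt kept most of their change. Pax6, Pdgfa, Diaph2, Kdelr3, Eef2kmt, Btg4 and B3gntl1 are among the genes that overlap a gene on the opposite strand, whose reads cannot be separated.

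Of the 21 gene lists, 5 passed the camera test at the 4-cell stage. Maternal oocyte transcripts fell, with a median log2 fold change of -0.90, 34 of 38 members below 0, 5 lower over all genes and 17 lower adjusted over the list alone (adjusted p = 2.16e-11). This call held with an estimated correlation (adjusted p = 0.037) and with fry (adjusted p = 0.0079). The mean log2 CPM of the 38 maternal members was 5.20 and 5.18 in siCon embryos 3 and 7 and 3.59 to 4.63 in the other 5 controls. Without both embryos the maternal median was -0.44, with 29 members below 0 and 0 lower either way in edgeR, and an adjusted p of 0.00048 (adjusted p = 0.76 with an estimated correlation).

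Cytosolic ribosomal protein genes were higher in siRif1 4-cell embryos, with a median of 0.17 and 80 of 87 members above 0 (adjusted p = 5.5e-08, and adjusted p = 0.60 with an estimated correlation). Without siCon embryos 3 and 7 their median was -0.04 (adjusted p = 0.52). Nuclear oxidative phosphorylation genes were higher by a median of 0.13, with 47 of 61 members above 0 (adjusted p = 0.00032, and adjusted p = 0.60 with an estimated correlation), and 0.14 without both embryos (adjusted p = 0.0045). Imprinted genes were higher by a median of 0.33, with 18 of 24 members above 0 (adjusted p = 0.00032, and adjusted p = 0.32 with an estimated correlation), and 0.10 without both embryos (adjusted p = 0.87). Pluripotency genes were higher by a median of 0.32, with 20 of 25 members above 0 (adjusted p = 0.0033, and adjusted p = 0.32 with an estimated correlation), and 0.05 without both embryos (adjusted p = 0.86). In these 4 lists edgeR called 0 members over all genes and 0 adjusted over the list alone. Members with the smallest p were Rps3a1 (0.71) and Rpl11 (0.24), Ndufb3 (0.52) and Uqcrq (0.48), Smoc1 (1.24) and Gab1 (0.68), and Dppa5a (0.61) and Stat3 (-1.26), with adjusted p from 0.14 to 0.55. Gab1 was at 1.22 and 0 CPM in siCon embryos 3 and 7 and at 17.5 to 50.8 CPM in the other 5 controls.

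The other 16 lists had adjusted p from 0.0705 to 0.935 at the 4-cell stage and medians from -0.32 to 0.13, with 7 in which median, mean and test differed in sign. Double-strand break repair genes had 2 of 45 members lower, H2afx and Chek1, over all genes and adjusted over the list alone. The count of 67 genes rested on few embryos. It was 9 without siCon embryo 3, 9 without siCon embryo 7 and 2 without both, namely Rif1 (-1.35, SE 0.27, adjusted p = 0.0499) and Gpr137b (0.81, SE 0.15, adjusted p = 0.026), the latter chosen after its values were seen. It was 231 without siCon embryo 1, 129 without siCon embryo 2, and 37, 43 and 40 without siRif1 embryos 8, 11 and 13. Of the 67 genes, 58 had the same sign without siCon embryos 3 and 7, and the median absolute log2 fold change went from 1.82 to 0.69. At an unadjusted p below 0.05 there were 1320 genes, against 592 expected by chance, and 841 without both embryos.

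**Figure D2:**
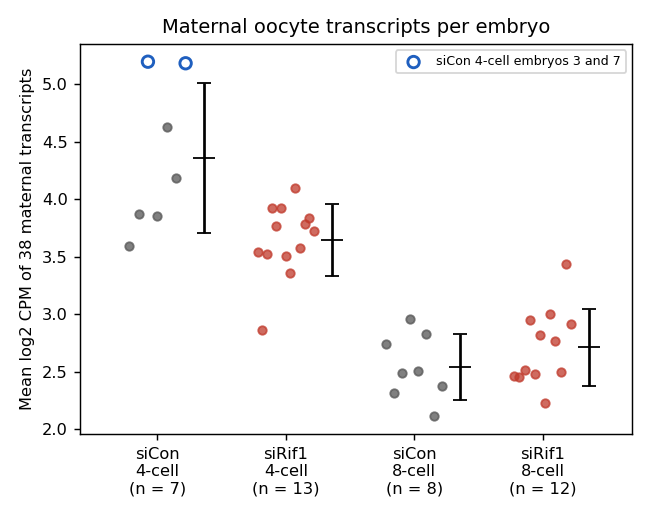
Mean log2 CPM of the 38 maternal oocyte transcripts (vertical axis) in each embryo (points) of the 4 groups, with the mean and SD (bars). Open circles mark siCon 4-cell embryos 3 and 7, at 5.20 and 5.18, above the 3.59 to 4.63 of the other 5 controls.

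The 8-cell comparison asked the same of embryos about a division later. Dpf3, which encodes a histone reader of the BAF chromatin remodelling complex (ENSMUSG00000021221, chromosome 12, 83213745 to 83487716), was the 1 gene past the threshold. It rose from 6.26 ± 1.99 CPM in siCon embryos (n = 8) to 17.9 ± 6.37 CPM in siRif1 embryos (n = 12), which is 2.83-fold (SE 0.29 on the log2 scale, edgeR adjusted p = 0.047), and 10 of 12 siRif1 embryos lay above all controls. At an unadjusted p below 0.05 there were 349 genes, fewer than the 592 expected by chance. The p53 target Sesn2, a stress-induced sestrin, was at 0.78 (SE 0.21, p = 0.0006 in edgeR), and the mitotic kinase Nek2 at 0.64 (SE 0.18, p = 0.0011). H2afx was at -0.80 (SE 0.37, p = 0.037), with 7 of 12 siRif1 embryos below all controls. None of these 3 passed the adjusted threshold.

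By camera 5 lists differed at the 8-cell stage, all by small amounts, and all 5 calls were lost with an estimated correlation. Nuclear oxidative phosphorylation genes were lower by a median of -0.10, with 51 of 61 members below 0 (adjusted p = 0.00024, and adjusted p = 0.68 with an estimated correlation). With ERCC totals as size factors their median was -0.00048, or -0.07 relative to the median of all genes. Cytosolic ribosomal protein genes were lower by a median of -0.06, with 70 of 87 members below 0 (adjusted p = 0.021, and adjusted p = 0.91 with an estimated correlation), and with ERCC totals as size factors the median was 0.02, or -0.05 relative to the median of all genes. Trophectoderm and compaction genes were higher by 0.16, with 30 of 40 members above 0 (adjusted p = 0.0058, and adjusted p = 0.68 with an estimated correlation). The p53 targets were higher by 0.16, with 23 of 32 above 0 (adjusted p = 0.021, and adjusted p = 0.68 with an estimated correlation), and maternal transcripts by 0.17, with 27 of 38 above 0 (adjusted p = 0.027, and adjusted p = 0.68 with an estimated correlation). With ERCC totals the maternal median was 0.09, and 0.02 relative to the median of all genes. No member of these lists passed over all genes, and adjusted over the list alone 1 p53 target did (Sesn2). Values of members were Ndufv2 -0.33, Ndufa3 -0.44, Rps2 -0.38, Rpl36 -0.21, Id2 1.86, Tspan8 0.69, Plk2 1.51, Cnot7 0.38 and Nlrp5 0.60. The other 16 lists had adjusted p from 0.105 to 0.997, and 5 of them differed in sign between median, mean and test.

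The single 8-cell call depended on the embryos used. The count was 0 without any of siCon 8-cell embryos 1, 2, 3, 4, 5 and 8 or siRif1 8-cell embryos 1, 2, 3, 5, 6, 7, 11 and 12, and 2 without siCon embryo 6. DESeq2 also called 1 gene and limma-voom 0.

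The comparison of 8-cell with 4-cell siCon embryos gave the difference between the stages in embryos injected with control siRNA. In edgeR 3554 genes changed, 1628 higher and 1926 lower at the 8-cell stage, of which 2240 changed at least 2-fold. With ERCC totals as size factors the balance turned, to 1799 higher and 425 lower. Crip2, which encodes a LIM domain protein (ENSMUSG00000006356, chromosome 12, 113140236 to 113145506), rose from 5.33 ± 6.04 CPM (n = 7) to 133 ± 75.8 CPM (n = 8), a log2 fold change of 4.65 (SE 0.53, adjusted p = 3.2e-08). Other increases were the helix-loop-helix inhibitor Id3 (4.50), the surface antigen Ly6a (4.50), Dap (4.01), the pluripotency factor Tfcp2l1 (3.86), the syndecan Sdc4 (3.72), the growth factor Pdgfa (3.60), the T-box factor Tbx20 (3.59) and Vnn1 (3.54). Zbed3 fell by 4.94, C86187 by 4.63, Bmp15 by 4.26 and Btg4 by 4.26 on the log2 scale. Their 4-cell means were carried in part by siCon embryos 3 and 7, without which the values were -3.23, -2.48, -2.47 and -2.64, all still past the threshold. The growth factor gene Fgf4 fell by 4.39, from 148 ± 68.6 to 6.93 ± 5.86 CPM (-4.19 without both embryos), and the Akt coactivator Tcl1 by 4.33 (-3.18). The remaining named decreases were D6Ertd527e (-3.89, or -2.60 without both), Trim61 (-3.72, or -2.90), Accsl (-3.11, or -2.38) and Pkd1 (-3.08, or -1.84).

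Maternal oocyte transcripts fell as a list between the stages, with a median of -2.27, 29 of 38 members lower and 1 higher, and 34 lower and 2 higher adjusted over the list alone (camera adjusted p = 3.3e-14, and adjusted p = 0.017 with an estimated correlation). Omt2a (-2.87) and Nlrp4f (-3.73) were lower, while Khdc3, a member of the subcortical maternal complex, was higher (3.07). Without siCon 4-cell embryos 3 and 7, which held the most maternal transcripts, the median was -1.71. Cytosolic ribosomal protein genes rose, with 77 of 87 members higher and 1 lower and a median of 0.79 (79 and 1 adjusted over the list alone, adjusted p = 3.95e-31, and adjusted p = 0.057 with an estimated correlation). Their median was 0.58 without both embryos. Rpl36 (1.17) and Rpl38 (1.04) were higher, and the muscle-type paralog Rpl3l was lower (-2.19, adjusted p = 0.020). Nuclear oxidative phosphorylation genes rose, with 39 of 61 members higher, 0 lower and a median of 0.62 (41 and 0 adjusted over the list alone, adjusted p = 1.2e-13, and adjusted p = 0.035 with an estimated correlation). Uqcrb of complex III was at 1.45 and the ATP synthase subunit Atp5j at 1.00.

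Trophectoderm and compaction genes rose, with 12 of 40 members higher and 4 lower and a median of 0.46 (14 and 4 adjusted over the list alone, adjusted p = 0.0027, and adjusted p = 0.15 with an estimated correlation). Cdx2, the trophectoderm transcription factor (ENSMUSG00000029646, chromosome 5, 147300805 to 147307270), had 0 counts in all 7 siCon 4-cell embryos and 6.70 ± 8.25 CPM in siCon 8-cell embryos (n = 8). Against a floor of 3 counts over the 4-cell group (0.131 CPM) it was at least 51.2-fold higher, and the list median with Cdx2 at this bound was 0.46. Klf5, also of this list, rose by 1.69 (SE 0.25).

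Double-strand break repair genes had 16 of 45 members lower and 2 higher, with a median of -0.57 (18 and 2 adjusted over the list alone, adjusted p = 0.0025, and adjusted p = 0.035 with an estimated correlation). Trp53bp1, the repair factor upstream of Rif1, fell by 1.90 and Fancd2 of the Fanconi pathway by 1.77, while the end-processing nuclease Dclre1c rose by 1.56. The list median was -0.30 without siCon 4-cell embryos 3 and 7 (adjusted p = 0.0046). The p53 targets had 8 of 32 members lower and 2 higher, the same counts adjusted over the list alone, with a median of -0.53 (adjusted p = 0.010, and adjusted p = 0.33 with an estimated correlation). Rrm2b (-2.62) and Sesn2 (-2.05) were lower and Perp higher (3.30). Mitotic genes had 11 of 42 members lower and 0 higher, also adjusted over the list alone, with a median of -0.32 (adjusted p = 0.019, and adjusted p = 0.50 with an estimated correlation). The kinesin Kif2c (-1.65) and the phosphatase Cdc25c (-1.30) were among them. With ERCC totals as size factors the median of all genes moved from -0.03 to 0.49, and the medians of these 3 lists turned to 0.0054, 0.08 and 0.13. Relative to the median of all genes under that scaling they were -0.48, -0.40 and -0.36.

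The remaining 14 lists did not pass between the stages (adjusted p from 0.090 to 0.822), and 3 of them differed in sign between median, mean and test. Pluripotency genes had 7 of 25 members higher and 4 lower (10 and 4 adjusted over the list alone). Pou5f1, the core pluripotency factor, rose by 2.19 (SE 0.27), and Klf17 fell by 2.82 (SE 0.29) from 617 ± 251 to 87.2 ± 46.8 CPM. Primitive endoderm genes had 4 of 13 members higher and 1 lower (5 and 1 adjusted over the list alone), with Gata6 at 2.23, Dab2 at 2.00 and Gata4 at -1.35. Leaving out each library in turn gave 3016 to 3582 changed genes, and leaving out siCon 4-cell embryos 3 and 7 gave 2657.

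**Figure D3:**
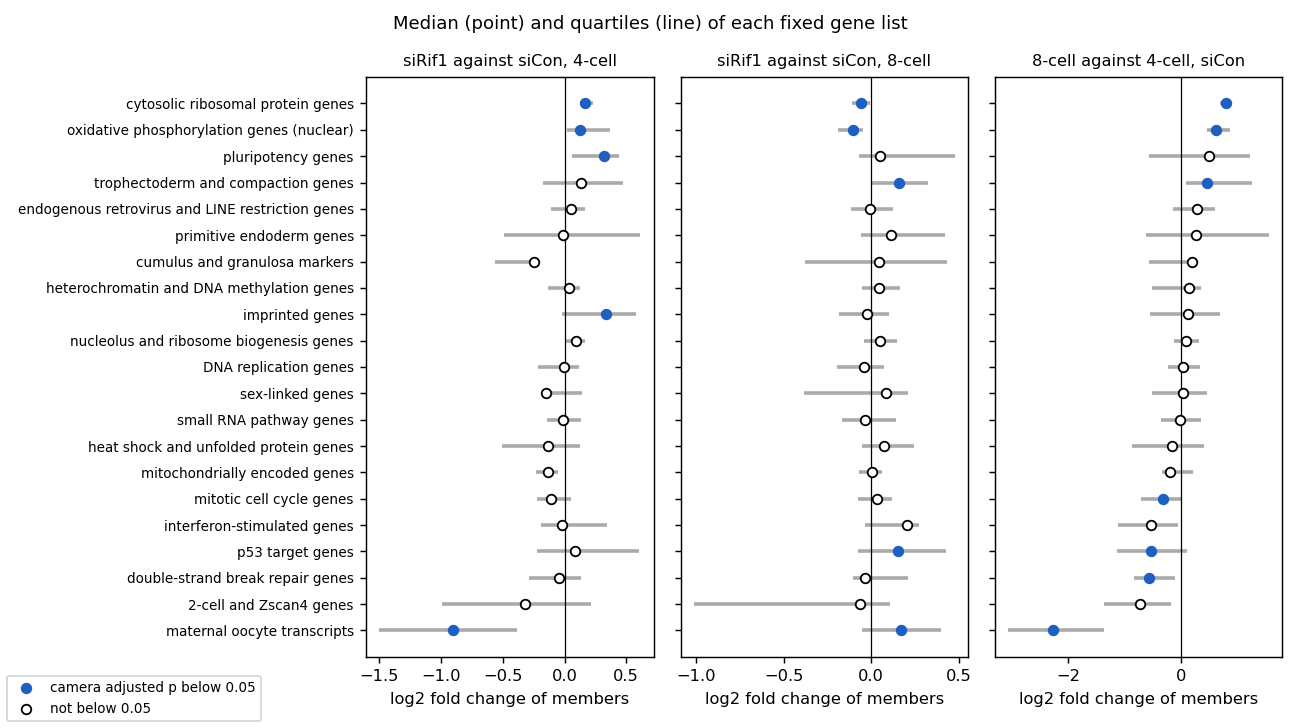
Median (points) and quartiles (lines) of the log2 fold changes (horizontal axis) of the members of 21 gene lists in 3 comparisons, with filled points where the camera adjusted p is below 0.05. Maternal transcripts lie at -0.90 in siRif1 4-cell embryos and at -2.27 between the stages. With ERCC totals as size factors the 8-cell ribosomal protein median turns to 0.02, and the stage medians of double-strand break repair, p53 and mitotic genes turn to 0.0054, 0.08 and 0.13. Relative to the median of all genes under that scaling these 4 medians stay negative, at -0.05, -0.48, -0.40 and -0.36.

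The interaction asked whether the siRif1 effect differed between the stages. EdgeR called 0 genes (smallest adjusted p = 0.18), limma-voom 0 and DESeq2 10, and 734 genes had an unadjusted p below 0.05 in edgeR against 592 expected. The count was 3 without siCon 4-cell embryo 1. The 5 named genes were Ncoa2 (2.83), Fam199x (2.14), the RNA-binding protein gene Elavl2 (1.88), Sdf2l1 (1.61) and Fra10ac1 (-1.50), with adjusted p from 0.20 to 0.29. Ncoa2 was at 0.86 without siCon 4-cell embryos 3 and 7. As a list, maternal transcripts differed between the stages by a median of 1.08, with 35 of 38 members above 0 and 9 higher adjusted over the list alone (camera adjusted p = 8.5e-13, and adjusted p = 0.020 with an estimated correlation). Without siCon 4-cell embryos 3 and 7 the difference was 0.63 (adjusted p = 3.5e-06).

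No gene was called in the same direction at both stages, against 0.0013 expected from independent lists of 67 genes and 1 gene by edgeR, and DESeq2 likewise gave 0. Of the 68 genes called at either stage, 36 had the same sign at both.

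The stage score placed each embryo between the siCon 4-cell and 8-cell profiles of 235 rising and 510 falling genes. It was 0.25 ± 0.36 in siRif1 4-cell embryos (n = 13) and -0.02 ± 0.32 in even-numbered siCon embryos (n = 3), a difference of 0.27 (exact two-sided permutation p = 0.264, where the smallest possible was 0.0036). At the 8-cell stage it was 2.85 ± 0.32 (n = 12) against 2.65 ± 0.10 (n = 4), a difference of 0.21 (exact two-sided permutation p = 0.234). When even-numbered controls chose the genes, the 4-cell difference was 0.43 (exact permutation p = 0.0076) against odd-numbered controls, which include siCon embryos 3 and 7, and the 8-cell difference was -0.14 (exact permutation p = 0.503). The log2 ratio of mouse to ERCC counts was 5.00 ± 0.54 in siRif1 (n = 13) and 4.83 ± 0.75 in siCon 4-cell embryos (n = 7), a difference of 0.17 (exact permutation p = 0.544). Without siCon embryos 3 and 7 this difference was -0.05. At the 8-cell stage the ratio was 5.77 ± 0.52 (n = 12) against 5.69 ± 0.32 (n = 8), a difference of 0.07 (exact permutation p = 0.722).

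Beside their high maternal transcripts, siCon 4-cell embryos 3 and 7 had low levels of some imprinted genes. Snrpn, which is expressed from the paternal allele, was at 0.977 and 2.08 CPM in embryos 3 and 7 and at 34.6 to 98.3 CPM in the other 18 4-cell embryos. Kcnq1ot1, an imprinted noncoding RNA made from the paternal allele, had 0 counts in both, which allows up to 0.733 and 0.780 CPM, and was at 3.41 to 112 CPM in the other 18. Impact was at 4.64 and 14.0 CPM against 21.1 to 91.8 CPM, and Slc38a4 had 0 counts in both (the same bounds) against 0.757 to 25.3 CPM. The bound in embryo 7 exceeds the lowest of these Slc38a4 values, so there it was not separated. Of 11 paternally expressed imprinted genes taken as a set, 7 lay below all other 18 in both embryos, while Usp29 (43.5 and 13.5 CPM against 5.86 to 52.0 CPM), Zdbf2 and Inpp5f lay within their range in both and Mest in embryo 7 alone. Among the 7, Peg3 and Zrsr1 had 0 counts in both. Their bounds exceed the lowest other embryo (0.293 and 0.679 CPM), so neither was separated from the others. Outside this set, the imprinted gene Igf2r was also below the other 18 in both embryos (260 and 154 CPM against 369 to 554 CPM). So was the imprinted gene Gab1, at 1.22 CPM in embryo 3 and 0 CPM in embryo 7, against 17.5 to 61.6 CPM. Jade1 was at 0 CPM in embryo 3 but at 83.4 CPM in embryo 7, against 14.7 to 87.6 CPM. The genes named here and the count of 7 were chosen after their values were seen.

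**Figure D4:**
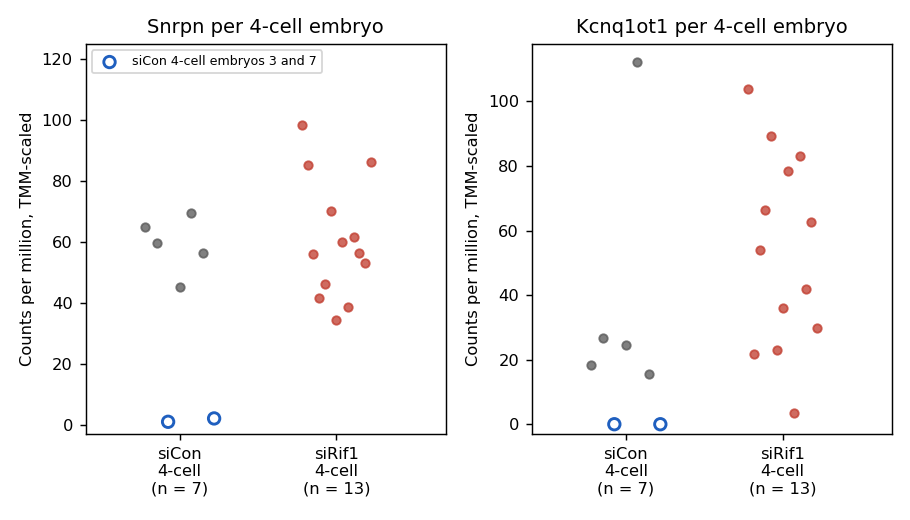
Snrpn (left) and Kcnq1ot1 (right) in CPM (vertical axes) in each 4-cell embryo (points) by group. Open circles mark siCon embryos 3 and 7, at 0.977 and 2.08 CPM for Snrpn and at 0 for Kcnq1ot1, below the other 18 embryos.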

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

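The values without siCon 4-cell embryos 3 and 7 and the grouping of splits by these embryos were chosen after the result was seen. The other tests in this part were set before they were run, with some bounds derived from the results with all libraries.

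Maternal oocyte transcripts stood out because the siRif1 effect differed between the stages, by 1.08 (camera on the interaction, adjusted p = 8.5e-13): their median was -0.90 at the 4-cell stage and 0.17 at the 8-cell stage. Leaving out siCon 4-cell embryos 3 and 7 moved the 4-cell median to -0.44. This lies between the bounds for an effect of those embryos alone (above -0.3) and an effect apart from them (below -0.6), so both remain open. The bounds were set before this fit, but the lower was derived from the median with all libraries. Leaving out each of the other 20 pairs of controls gave maternal medians from -1.20 to -0.66, all below -0.44. These fits gave a median of 86 called genes, with 102 to 367 where neither embryo was in the pair and 5 to 70 where 1 was. Where neither was in the pair, embryos 3 and 7 weigh more among the remaining controls. The counts therefore cannot decide on a loss of power from having 2 fewer controls. Within the 13 siRif1 4-cell embryos the maternal score had r = -0.16 with the Rif1 level (rho = -0.02, permutation p = 0.593 and 0.955, adjusted p = 0.593 and 0.955 over 2 relations, r = -0.06 without the 2 farthest embryos) and r = -0.38 with the mouse to ERCC ratio (rho = -0.29, permutation p = 0.183 and 0.345, adjusted p = 0.365 and 0.691, r = -0.21 without the 2 farthest). Their 95% bootstrap intervals (-0.48 to 0.52 and -0.73 to 0.045) leave dose and RNA content as explanations that cannot be told apart from none at this number of embryos, and a biological effect of Rif1 depletion on maternal transcripts stays open too.

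For the 67 genes of the 4-cell comparison 3 of 100 splits, the real one included, gave as many. The highest other split gave 1013 genes, many times the real count, which points to a structure of the samples. All 3 splits at or above 67 had siCon embryos 3 and 7 together in the group of 7, and the 8 such splits had a median of 50.5 genes, while splits with these embryos apart or both in the group of 13 reached at most 4 and 3. The splits therefore do not exclude that the count came from the chance placing of these embryos among the controls. For the 8-cell comparison 3 of 100 splits, the real one included, gave at least the real 1 gene, and the highest other also gave 1, so a count this small does not exclude chance. For the stage comparison the splits argue against chance, as 1 of 100 splits, the real one with 3554 genes, was as large. This is the smallest share that 100 splits can give. The highest other gave 1634 genes, and 28 other splits called some. For the interaction the splits decide nothing, since with a real count of 0 in edgeR (734 genes at an unadjusted p below 0.05, 10 in DESeq2 and 0 in limma-voom) all 100 splits give as many, and the highest other gave 1.

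The siRif1 effect also differed between the stages by camera for 4 other lists, with the difference taken as 8-cell minus 4-cell. Nuclear oxidative phosphorylation genes differed by -0.23 (adjusted p = 7.9e-09, and adjusted p = 0.25 with an estimated correlation), and by -0.22 without siCon embryos 3 and 7. Cytosolic ribosomal protein genes differed by -0.21 (adjusted p = 1.7e-10, and adjusted p = 0.60 with an estimated correlation), and by -0.01 without them. Imprinted genes differed by -0.28 (adjusted p = 0.0043, and adjusted p = 0.47 with an estimated correlation), and by -0.09 without them. Heat shock and unfolded protein genes differed by 0.29 (adjusted p = 0.0043, and adjusted p = 0.36 with an estimated correlation), and by 0.11 without them. The other 16 lists had adjusted p from 0.133 to 0.964, with 5 sign differences between median, mean and test. The Rif1 effect differed by 0.75, with an unadjusted edgeR p of 0.034 and an adjusted p of 0.74.

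In 2 of 26 checks of a measure within a siCon group, 1 embryo lay far from the others, where chance gives about 1 in 20. The measures covered library quality, and also the Rif1 level, maternal score, summed paternal imprinted genes and stage score. The larger siRif1 groups were not checked. The 50 most abundant genes took 47.8% of counts in siCon 4-cell embryo 5 and 25.8% to 32.2% in the other controls (gap over range 0.708, above its critical value). Multimapping reads made up 6.84% in siCon 8-cell embryo 8 and 5.21% to 5.71% in the others (0.692, also above its critical value). The check flags only 1 embryo apart from all others, so 2 alike embryos hide each other. It could therefore not flag siCon 4-cell embryos 3 and 7 where they lay together. Their multimapping reads made up 7.06% and 6.90%, against 5.47% to 6.38% in the other siCon 4-cell embryos.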

How the results depend on the processing

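The alternatives without siCon 4-cell embryos 3 and 7 and with Y-linked expression as a covariate were chosen after seeing the data, and the others were fixed beforehand. The 67 genes of the 4-cell comparison became 322 with no filter on low counts, 192 in DESeq2, 4 in limma-voom, 2 in a fit of the compared groups alone, 0 with a replicate block (edgeR), 4 with ERCC totals as size factors and 2 without embryos 3 and 7. They stayed within 1.5 times (52 to 70) with RLE factors, without the shallow library, without chromosomes X and Y, with the Y-linked covariate and with a 2-fold minimum. Leaving out each library gave 9 to 231 genes, with the values of single embryos given beside the result. The single 8-cell gene became 0 with no filter, limma-voom, the compared groups alone, a replicate block, no shallow library and ERCC factors, and 0 to 2 in leave-one-out. The 3554 stage genes became 1845 with a replicate block, 2224 with ERCC factors (1799 higher, 425 lower) and 2240 with a 2-fold minimum, which passes fewer genes by construction. They numbered 3016 to 3582 in leave-one-out and 2657 to 3948 under the other alternatives. The interaction count of 0 became 10 in DESeq2 and 0 to 3 in leave-one-out, and stayed at 0 under 10 other alternatives. The 4-cell Rif1 change lost its call at -1.27 in the compared groups alone (adjusted p = 0.060), -1.19 with a replicate block (adjusted p = 0.29) and -1.10 with ERCC factors (adjusted p = 0.60), and kept it under 6 others (adjusted p = 0.00031 to 0.0499). The 5 lists of the 4-cell comparison became 1 with an estimated correlation, 8 with no filter and 2 without embryos 3 and 7. The 5 lists at the 8-cell stage became 0, and the 7 between the stages became 3, with an estimated correlation, and the latter 11 with no filter. The stage score difference at the 4-cell stage passed its test at 0.43 (exact permutation p = 0.0076) and that at the 8-cell stage turned to -0.14 when even-numbered controls chose the genes. The 4-cell ratio of mouse to ERCC counts turned to -0.0475 without embryos 3 and 7. Among named genes, B3gntl1 (0.26) and Dhcr7 (0.26) turned without embryos 3 and 7 and Dhcr7 (0.0897) in limma-voom, and the uncalled stage value of Rif1, -0.45, turned to 0.0579 with ERCC factors. Of 107 named values, 102 kept direction and side of the threshold in DESeq2, 85 in limma-voom, 80 with a replicate block and 76 with ERCC factors, as did 71 of 94 without embryos 3 and 7 and 78 of 101 in the compared groups alone. Of the 30 values from the 4-cell siRif1 comparison, 8 did so without embryos 3 and 7. The count was also 8 in the compared groups alone and with a replicate block, 10 with ERCC factors and in limma-voom, and 29 in DESeq2. Of the 58 stage values, 57 did so without embryos 3 and 7. Except for the 2-fold minimum, the estimated correlation and fewer embryos, the cause was not tested. Replicate numbers did not pair samples: residual correlations of equally numbered siCon and siRif1 embryos were -0.10 to 0.17 over 7 pairs at the 4-cell stage and -0.20 to 0.17 over 8 pairs at the 8-cell stage, so the replicate block removes degrees of freedom without a shared factor. At this depth and number of embryos, changes near 1.5-fold are mostly missed, as 4.48% of simulated ones were recovered at the 4-cell stage.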

Other observations

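The stage differences in this part follow the fixed lists, while the tests of stage, of transcription and of Snrpn, Kcnq1ot1, Peg3 and Zrsr1 in siCon 4-cell embryos 3 and 7 were chosen after those embryos had been seen to stand apart.

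Several lists that did not pass as a whole between 4-cell and 8-cell siCon embryos held members that moved in opposite directions. Among heterochromatin and DNA methylation genes 4 of 49 members were higher and 11 lower at the 8-cell stage (5 and 11 adjusted over the list alone). The methylcytosine dioxygenase Tet3, which acts on the zygotic genome, fell by 2.11 on the log2 scale (SE 0.39, edgeR adjusted p = 6.4e-05), while its paralog Tet2 rose by 2.59 (SE 0.44, adjusted p = 1.8e-05). Zfp57, which protects methylation at imprinted loci, fell by 1.95, and the Polycomb subunit Eed rose by 0.79. Among heat shock and unfolded protein genes 4 of 26 were higher and 8 lower (4 and 9 adjusted over the list alone). The cytosolic chaperones Hsp90aa1 (1.33) and Hsp90ab1 (0.85) rose, from 968 ± 244 to 2432 ± 636 CPM for Hsp90aa1, and the endoplasmic reticulum chaperone Hspa5 fell by 1.66, from 387 ± 152 to 122 ± 40.1 CPM (n = 7 and 8).

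DNA replication genes had 4 of 57 members higher and 7 lower (the same adjusted over the list alone): thymidylate synthase Tyms rose by 1.44 and the clamp loader subunit Rfc3 by 1.47, while the Cdc7 kinase activator Dbf4 (-0.90) and the fork protein Tipin (-0.55) were lower. Nucleolus and ribosome biogenesis genes had 7 of 50 higher and 3 lower (7 and 3), among them Nhp2 (0.81) and Taf1c (1.53). In the small RNA pathway 2 of 16 were higher and 3 lower (2 and 4), with the slicer Ago2 at 1.06 and Dicer1 at -0.72. The counts higher and lower were 6 and 1 of 21 for retrovirus and LINE restriction genes (6 and 1 adjusted over the list alone), 0 and 4 of 11 for interferon-stimulated genes (0 and 4), 0 and 3 of 20 for 2-cell genes (0 and 1), 1 and 4 of 24 for imprinted genes (0 and 4), 1 and 1 of 15 for mitochondrially encoded genes (0 and 0), and 0 and 1 both of 14 sex-linked genes and of 5 cumulus and granulosa markers (0 and 1 each).

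Embryos 3 and 7 of the siCon 4-cell group may lack an active paternal genome, a hypothesis formed on these data. If so, paternally expressed imprinted genes would be near absent: the sum over 11 such genes was 33.6% and 24.8% of the median of the other 5 controls, between the values set beforehand for absence (10%) and presence (50%), so this test leaves the question open. Usp29 gave 43.5 of the 65.2 CPM in embryo 3, and without it the sums were at 13.7% and 21.8%, still between these values. Over Snrpn, Kcnq1ot1, Peg3 and Zrsr1 alone the higher embryo had 3.79% of the lowest other 4-cell library, but these genes were picked for this pattern and cannot decide it. Igf2r and Gab1, imprinted genes outside the 11 of the sum, were also below all other 4-cell embryos in both embryos. Igf2r was at 260 and 154 CPM against 369 to 554 CPM, and Gab1 at 1.22 and 0 CPM against 17.5 to 61.6 CPM. Low levels were therefore not confined to the 11 genes. The parental allele of the reads was not measured, so Igf2r and Gab1 do not count for or against the hypothesis. The sum over 4 Y-linked genes was below 1 CPM in both embryos, and Xist was at 0.244 and 24.2 CPM against 85.9 to 755 CPM in the other 8 4-cell embryos with a Y-linked sum below 1 CPM.

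An earlier stage of development is a candidate explanation for the same embryos. On stage genes chosen in even-numbered controls they scored -1.58 and -1.54, against -1.23 and -1.15 in the other 2 odd-numbered controls, a gap of 0.31 that exceeded the SD of 0.221 among siRif1 4-cell embryos. The gap to the lowest siRif1 4-cell embryo was 0.12, within that SD, so the answer depends on the reference and stays open. For embryonic transcription that had not yet begun, the measure was the level of genes higher at the 8-cell stage. They were 0.047 lower in the higher of both embryos than in the lowest siRif1 embryo, within the SD of 0.162. Against the lower of the other 2 odd-numbered controls they were 0.26 lower. Genes that rise between these stages do not measure whether transcription had begun before, so this test cannot decide it. The hypotheses do not exclude each other, and genotypes of the embryos would be needed to separate them.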
